A study of Bos taurus with 9 samples.

How the data were processed

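Gene expression was measured on 9 Affymetrix bovine arrays hybridised with total RNA from primary cultures of bovine adrenal chromaffin cells. There were 3 arrays each for untreated cells, cells given 100 nM PACAP for 6 h and cells given 10 nM TNF-alpha for 6 h. Each array was assigned to its group, and given its replicate number, from its sample title. The series design text calls the arrays technical repeats, and no label says whether they came from separate cultures or animals. All p-values therefore measure the spread between arrays, which may be technical, and not the spread between animals. Agilent arrays named in the design text were not analysed here.

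The values deposited by the authors are log2 expression values, 1 per probeset and array. Per the submitters' processing notes they were made with Affymetrix Expression Console and RMA, a method that corrects background, equalises array distributions and summarises the probes of a probeset; versions and settings are not given in the sources used here. Per the labels' protocols, 5 ug of total RNA went into each one-cycle biotin labelling reaction. The background correction could not be varied, because it was done before these values were made. RMA values compress changes near the low end of the scale, so folds of dim probesets are understated. The number of arrays limits the precision, and no detection calls were used.

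The table held 24128 probesets. The 112 control probesets were left out, and 24016 were tested. The file does not pair probeset IDs with gene names, and 0 of the IDs matched the gene table used for names. Gene symbols are therefore not given, and the 26 gene lists fixed before the data were examined, among them markers of other adrenal cell types, could not be tested. The rule for naming genes was therefore applied to probesets, as the 2 with the largest rise and the 2 with the largest fall among those called in each comparison with untreated cells; they are described by rank, and the IDs of the first of each kind head the panels of the plot of single arrays. The parts of the rule that need gene names were not applied. The exception is a set of 18 bovine control probesets, whose IDs carry the names of 6 genes; these were chosen after their values were seen.

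The tests were run with limma 3.58.1 in R 4.3.3. Group means were fitted to all 9 arrays together, so that the 3 groups shared 1 estimate of the spread (6 residual degrees of freedom), followed by empirical Bayes moderation. The 3 contrasts were PACAP against untreated, TNF against untreated and PACAP against TNF. Tests were two-sided, and Benjamini-Hochberg adjustment was made within each contrast over all probesets tested. A probeset was called at an adjusted p under 0.05, and calls of at least 2-fold were counted as well. A fold is 2 raised to the difference of mean log2 values. Errors of fold changes are the moderated standard errors (SE).

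The procedure was tested on simulated data built from the measured means and variances. For PACAP against untreated, simulated among 24016 probesets, the fit recovered 31 of 50 probesets changed 1.5-fold, 44 of 50 changed 2-fold and 50 of 50 changed 4-fold, with 4 false calls. For TNF against untreated the numbers were 25 of 50, 46 of 50 and 49 of 50, with 5 false calls. The simulated arrays were drawn independently, without the links between arrays by replicate number described next. Recovery and false calls on the real arrays may therefore differ.

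The groups share replicate numbers. Deviations of the arrays from their group means correlated between groups at 0.23 to 0.47 for replicate 1, 0.41 to 0.53 for replicate 2 and 0.57 to 0.65 for replicate 3. Every same-numbered pair was over the threshold of 0.1, so by that rule the numbers were taken to pair the arrays, though no label explains the numbers. Replicates 1 and 2 of different groups correlated as well, at 0.09 to 0.61, so passing the threshold does not show that 1 goes with 1 or 2 with 2. Of the 9 arrays, 6 correlated best with an array of their own number, among them the replicate 3 arrays. The values thus part replicate 3 from replicates 1 and 2, while the pairing within replicates 1 and 2 rests on the numbers alone. A fit with the replicate number as a block was run beside the main one.

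Alternatives chosen before the data were examined were filters on dim probesets, 3 other normalizations, an intensity trend with a robust prior, array weights, fits of 6 arrays, the replicate block, a threshold of 0.01 and leaving out each array in turn. Alternatives added after seeing the data were a block that parts replicates 1 and 2 from replicate 3, replicates 1 and 2 averaged into 1 unit per group together with the replicate block, and a fit within replicates 1 and 2; the control probesets were also added to the fit. The overlap of the treatments' calls was set beside the number that independent lists give and beside 100 simulated data sets in which neither treatment changes any probeset but both are compared with the same untreated arrays. For the covariance of the changes, 2 further sets of 100 were added after seeing the data. Both hold a replicate term; 1 draws independent residuals, and the other draws whole arrays of residuals of the block fit with random signs, so that probesets stay correlated.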

Results

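Chromaffin cells are the catecholamine- and peptide-secreting cells of the adrenal medulla. The study asked which genes respond in these cells to PACAP, a neuropeptide that acts as a transmitter at the adrenal medulla, and to TNF-alpha, an inflammatory cytokine, and whether the responses involve different genes. Expression was measured in 3 groups of 3 arrays, namely untreated cells, cells after 6 h with 100 nM PACAP and cells after 6 h with 10 nM TNF. Median log2 values of the arrays lay between 6.65 and 6.72. Within each group, replicates 1 and 2 resembled each other more than either resembled replicate 3. Across probesets, which are not independent replicates, replicates 1 and 2 correlated at 0.9985 in untreated, 0.9983 in TNF-treated and 0.9962 in PACAP-treated cells. Untreated replicate 3 correlated at 0.99 with untreated replicate 1 but at 0.993 with TNF replicate 3. Spike-in transcripts had a mean 3' minus 5' difference of 1.73 (log2) on TNF replicate 3 and of 1.15 to 1.37 on the other arrays.

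**Figure D1:**
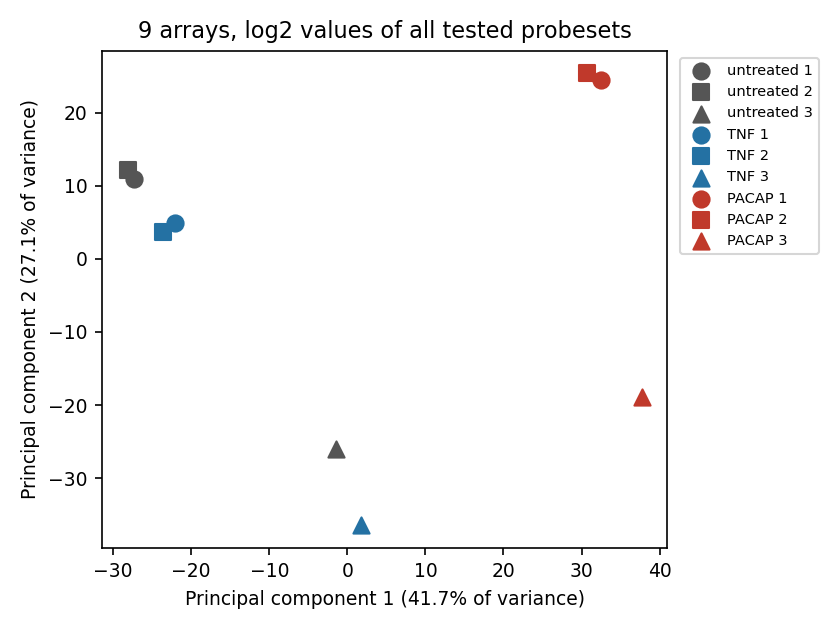
Scores of the 9 arrays on the first (41.7% of variance, x axis) and second (27.1%, y axis) principal components of the log2 values; colour marks the group and symbol the replicate number. The 3 PACAP arrays have the highest scores on the first component, from 30.7 to 37.7, and the replicate 3 array of each group has a second-component score below 0.

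PACAP changed the expression of more probesets than TNF did. Against untreated cells, 1430 of 24016 probesets were higher and 2040 were lower with PACAP (limma, adjusted p under 0.05), 14.45% of those tested. At least 2-fold changes were called for 296 probesets upwards and 215 downwards, and at least 4-fold changes for 53 upwards and 7 downwards. With the replicate number as a block, 2206 probesets were higher and 3053 lower; with replicates 1 and 2 averaged into 1 unit and the block kept, 768 were higher and 990 lower; within replicates 1 and 2, 2907 were higher and 4001 lower. The counts of higher and lower probesets became 700 and 1034 without untreated replicate 1, 704 and 984 without untreated replicate 2, 922 and 1316 without PACAP replicate 1, and 895 and 1151 without PACAP replicate 2.

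The largest rise among the calls with PACAP was that of a probeset at 5.01 ± 0.33 (log2, SD, n = 3) in untreated and 11.71 ± 0.29 in PACAP-treated cells, a log2 change of 6.70 (SE 0.24) or 104-fold, with a limma adjusted p of 1.25e-05. The next largest was a rise of 6.25 (SE 0.65), or 75.9-fold, from 5.28 ± 1.36 to 11.53 ± 0.50 (limma adjusted p = 0.000702). With TNF these probesets stood at 5.06 ± 0.39 and 5.50 ± 0.82, and neither differed from untreated cells by the test (limma adjusted p = 0.978 and 0.958). The largest falls with PACAP were smaller than the largest rises. Those falls ended, and those rises started, toward the low end of the scale, where RMA compresses changes. No detection calls were used, so the folds are approximate and the ranking holds only for these values. The probeset with the largest fall among the calls fell by 2.60 on the log2 scale (SE 0.43), or 6.08-fold, from 7.05 ± 1.02 to 4.45 ± 0.22 (limma adjusted p = 0.00495). The next fell by 2.20 (SE 0.22), or 4.61-fold, from 7.19 ± 0.16 to 4.99 ± 0.51 (limma adjusted p = 0.000637). With TNF these falling probesets changed by -1.30 and -0.84 on the log2 scale and did not pass (limma adjusted p = 0.232 and 0.116). Between PACAP and TNF the former did not differ by the test (limma adjusted p = 0.104), while the latter did (0.0055).

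Probesets that fell at least 2-fold with PACAP had started at a median log2 level of 8.12 in untreated cells and reached 6.91, and 13.5% of them had been below the median untreated level of all probesets. Those that rose at least 2-fold had started at a median of 7.23 and reached 8.97, and 40.5% of them had been below that median. Both classes were chosen on these same values, and dim probesets have little room to fall 2-fold. The higher start of the falls is therefore at least partly built in by the selection. In the same-numbered pairs of arrays 1, 2 and 3, from which these probesets were chosen, the median log2 change of those that rose was 1.59, 1.55 and 1.11, and that of those that fell was -1.32, -1.33 and -0.90.

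TNF mainly raised expression among the larger changes. Of the probesets called at least 2-fold changed against untreated cells, 129 were higher and 8 were lower, and 32 of the former were at least 4-fold higher. Over calls of any size, 320 probesets were higher and 138 lower (limma, adjusted p under 0.05), 1.91% of those tested. With the replicate block 674 were higher and 606 lower, so that 52.7% of the calls were rises, against 69.9% without it. With replicates 1 and 2 averaged and the block kept, 122 were higher and 15 lower, and within replicates 1 and 2 the counts were 1415 and 1499. The counts of higher and lower probesets became 116 and 15 without untreated replicate 1, 108 and 12 without untreated replicate 2, 411 and 310 without untreated replicate 3, 124 and 18 without TNF replicate 1, and 107 and 16 without TNF replicate 2. They became 236 and 89 without PACAP replicate 1, and 212 and 72 without PACAP replicate 2, whose arrays enter only the estimate of the spread. Those of at least 2-fold became 81 and 3 without untreated replicate 1, 78 and 3 without untreated replicate 2, 80 and 4 without TNF replicate 1, and 75 and 3 without TNF replicate 2. Without untreated replicate 3, 28 were at least 2-fold lower.

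The probeset with the largest rise among the calls with TNF went from 5.59 ± 0.08 (log2, SD, n = 3) to 9.54 ± 0.67, a log2 change of 3.94 (SE 0.28) or 15.4-fold (limma adjusted p = 0.000276). The next rose by 3.91 (SE 0.21), or 14.99-fold, from 8.39 ± 0.47 to 12.30 ± 0.15 (limma adjusted p = 7.79e-05). With PACAP these probesets stood at 5.66 ± 0.16 and 7.81 ± 0.14, and neither differed from untreated cells by the test (limma adjusted p = 0.917 and 0.107). The probeset with the largest fall among the calls fell by 1.58 on the log2 scale (SE 0.21), from 8.76 ± 0.19 to 7.18 ± 0.35 (limma adjusted p = 0.00736), and the next fell by 1.54 (SE 0.27), from 6.39 ± 0.65 to 4.85 ± 0.17 (limma adjusted p = 0.0269). Both also changed with PACAP, where the former fell by 1.25 (limma adjusted p = 0.00487) and the latter fell by 2.09 (limma adjusted p = 0.0017). The former call with TNF was lost without untreated replicate 2 (limma adjusted p = 0.0504) or TNF replicate 2 (0.0524), within a range of 0.000173 to 0.0524 over all settings. The latter was lost in 10 of 21 other settings, with limma adjusted p-values from 2.24e-05 to 0.13, among them 0.13 without untreated replicate 1, 0.121 without untreated replicate 2, 0.108 without TNF replicate 1, 0.0981 without TNF replicate 2, 0.0585 without TNF replicate 3, 0.0511 without PACAP replicate 1 and 0.0548 without PACAP replicate 2. Over the settings the log2 change with TNF ran from -1.78 to -1.45 for the former and from -1.91 to -1.33 for the latter.

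The 129 probesets that rose at least 2-fold with TNF had a median log2 level of 6.51 in untreated and 8.37 in TNF-treated cells, and of 6.56 with PACAP. Their median changes were 1.67, 1.74 and 1.20 in the same-numbered pairs of arrays 1, 2 and 3.

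**Figure D2:**
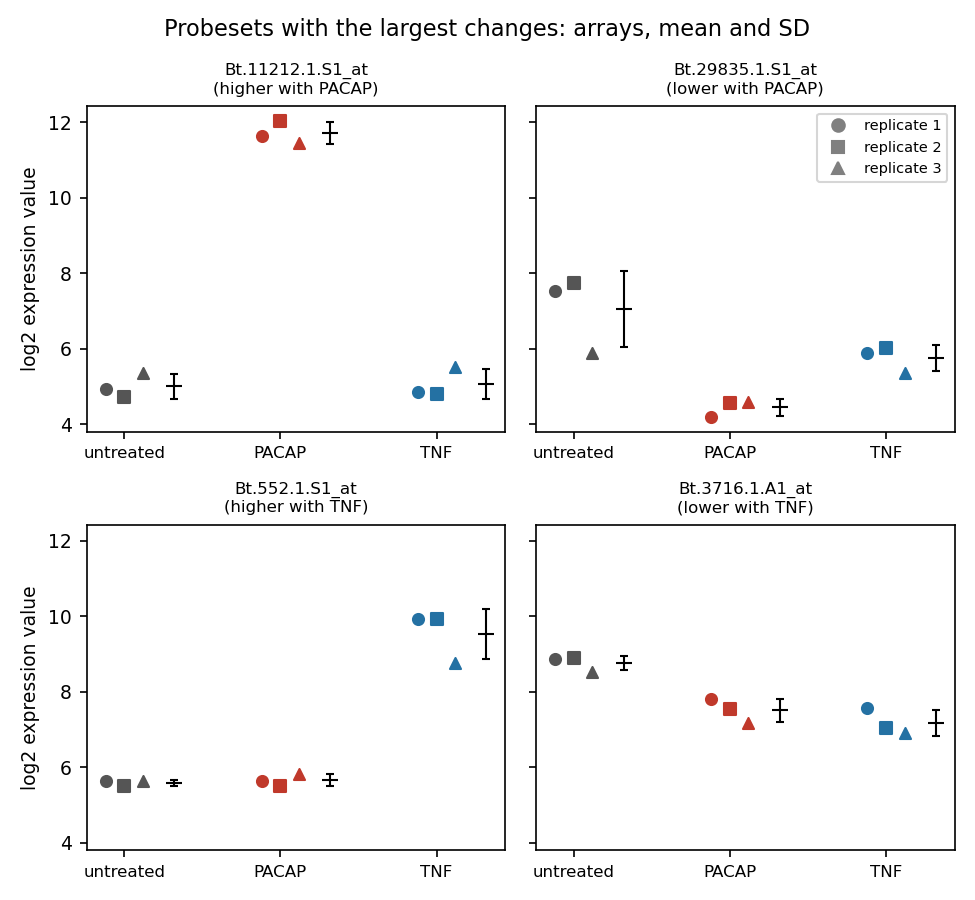
Log2 expression values (y axis, shared) of the probeset with the largest rise and the one with the largest fall among those called with PACAP (top) and with TNF (bottom), by group (x axis); points are single arrays with symbols for replicate numbers, and bars are the mean and SD of 3 arrays. The probeset that rose most with PACAP lies between 11.466 and 12.035 on the PACAP arrays and at or below 5.511 on the other 6.

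Compared directly, PACAP and TNF differed at 2179 probesets, of which 953 were higher and 1226 lower with PACAP than with TNF (limma, adjusted p under 0.05); the doses differed as well, at 100 nM and 10 nM. Most of the strong rises passed this test of the difference. Of the 296 probesets at least 2-fold higher with PACAP, 244 were also higher with PACAP than with TNF, and of the 129 at least 2-fold higher with TNF, 109 were higher with TNF than with PACAP. Both sets were chosen on PACAP or TNF arrays that enter this test again, which favours passing. The number that would pass for that reason was not estimated. The probeset with the largest rise with PACAP was higher with PACAP than with TNF by 6.65 on the log2 scale (SE 0.24, limma adjusted p = 8.65e-06). The probeset with the largest rise with TNF had a log2 difference of -3.87 between PACAP and TNF (SE 0.28, limma adjusted p = 9.75e-05). Of the 215 probesets at least 2-fold lower with PACAP, chosen in the same way, 152 were also lower with PACAP than with TNF. The probesets at least 2-fold higher with TNF had a median log2 change of 0.01 with PACAP, where 18 were called higher and 18 lower. Those at least 2-fold higher with PACAP had a median log2 change of 0.21 with TNF, where 17 were called higher. Those at least 2-fold lower with PACAP had a median log2 change of -0.38 with TNF, and the 8 at least 2-fold lower with TNF had one of -1.32 with PACAP, where 7 were at least 2-fold lower as well. These medians include what the shared untreated arrays add, which was not estimated for them, and rises and falls were not tested against each other. With the replicate block, 1656 probesets were higher and 2035 lower with PACAP than with TNF, and with replicates 1 and 2 averaged as well the counts were 514 and 581. The counts became 476 and 680 without TNF replicate 1, 489 and 630 without TNF replicate 2, 576 and 751 without PACAP replicate 1, and 569 and 691 without PACAP replicate 2.

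A smaller set of probesets was called with both treatments. There were 64 higher with both, 102 lower with both and 52 called in opposite directions, of which 46 were lower with PACAP and higher with TNF. Lists drawn independently with these sizes would share 19.05 rises and 11.72 falls and would hold 35.4 opposite calls. Those numbers take every probeset as equally likely to be called. An excess over them therefore does not by itself show that the 2 responses are linked. In 100 simulated data sets without any effect, the highest number called in both was 0 in either direction; almost nothing is called without effects, so this leaves open how many shared calls the common untreated arrays add to real ones. At least 2-fold changes were shared by 9 probesets upwards and 7 downwards. Of the 64 shared rises, 52 showed no called difference between the treatments, 6 were higher with PACAP and 6 were higher with TNF. With the replicate block, 189 probesets were higher with both, 413 lower with both and 107 opposite, and with replicates 1 and 2 averaged as well these counts were 10, 6 and 12. The numbers higher and lower with both became 14 and 12 without untreated replicate 1, 13 and 9 without untreated replicate 2, 186 and 260 without untreated replicate 3, 19 and 12 without TNF replicate 1, 16 and 12 without TNF replicate 2, 31 and 64 without PACAP replicate 1, and 28 and 50 without PACAP replicate 2. Opposite calls became 16 and 15 without untreated replicates 1 and 2 respectively, 24, 20 and 86 without TNF replicates 1, 2 and 3, and 32 and 30 without PACAP replicates 1 and 2.

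Across probesets, the log2 changes with PACAP and TNF had a covariance of 0.0344, against a median of 0.0120 in the simulated data, which comes from the shared untreated arrays; the difference was 0.0224. That simulation ignores the pairing by replicate number. With a replicate term the simulated median was 0.0057 and the difference 0.0287, and with whole arrays of residuals drawn, so that probesets stayed correlated, the median was 0.00675, the highest value 0.0256 and the difference 0.0276. The Pearson correlation of the changes with PACAP and TNF was 0.374 and the simulated median was 0.499. Changes with either treatment alone lower this correlation, so a value below that median does not count against shared changes. The same direction was seen at 69.07% of probesets, against a simulated median of 66.58% and a highest value of 67.41%. Probesets are not independent replicates. Part of the excess of shared calls may come from the shared untreated arrays, whose number was too small for them to be split between the comparisons with 2 arrays on each side.

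**Figure D3:**
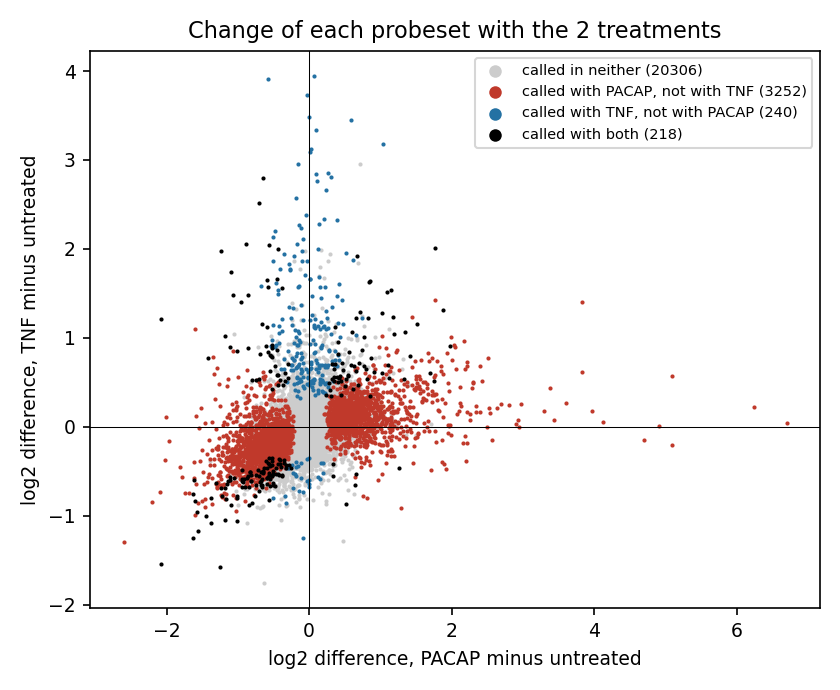
Log2 change of each of the 24016 probesets with PACAP (x axis) and with TNF (y axis), each against untreated cells; colours mark probesets called at an adjusted p under 0.05 with PACAP and not TNF (3252), with TNF and not PACAP (240), with both (218) or with neither (20306). The largest rises of each treatment lie close to the axis of that treatment.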

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

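The tests of the 5' signal in replicate 3, of a separate culture or processing day, of changes on arrays not in common (with all 3 of its no-change models) and of common handling, and the fit that holds the control probesets, were chosen after the result was seen.

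Replicate 3 of each group stood apart from the other arrays of its group, and the deviations of the replicate 3 arrays went together across groups. A difference between arrays that varies with intensity is argued against, since after cyclic loess the lowest of the 3 correlations between replicate 3 deviations was still 0.57. RMA had already equalised the array distributions, and these correlations were 0.57 to 0.65 before loess, so loess had little to remove. Other forms of incomplete normalization were not tested. A loss of 5' signal in the replicate 3 RNA is argued against too, since the mean 3' minus 5' difference of 6 bovine control genes was highest on replicate 3 in only 1 of the 3 groups (TNF, 0.654). A separate culture, animal or processing day for replicate 3 stays open, because no label ties the numbers to any of these and the correlation of at least 0.57 does not separate them; no biological explanation was tested.

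An interaction term of treatment with replicate 3 against replicates 1 and 2 (limma, adjusted p under 0.05) called 82 of 24016 probesets for PACAP and 3 for TNF, but replicate 3 is 1 array per group and the spread came only from replicates 1 and 2, which are close to each other, so the calls do not show that the effects differed. Across probesets, the changes in replicate 3 correlated with those in replicates 1 and 2 at 0.756 (PACAP) and 0.393 (TNF), against 0.855 and 0.812 between replicates 1 and 2, and 2 of the 3470 probesets called with PACAP and 0 of the 458 called with TNF, chosen on all 3 replicates, had the opposite sign in replicate 3. Poorer labelling of 5' parts on TNF replicate 3, where spike-in transcripts had a 3' minus 5' difference of 1.73, stays open for the TNF calls of this term. PACAP, whose replicate 3 array had a difference of 1.25, gave 27.33 times as many interaction calls; this had been set beforehand as evidence against the labelling, but a difference in PACAP arrays does not bear on the TNF array, and 3 TNF calls are too few by a limit set after the result was seen. The ratio of calls depends on the threshold, since at an unadjusted limma p under 0.05 more probesets passed for TNF than for PACAP. No biological explanation was tested, because no label says how replicate 3 differs.

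The changes with PACAP and TNF had a covariance across probesets of 0.0344 and the same direction at 69.07% of probesets (no-change median 66.58%). Their correlation was 0.374 (no-change median 0.499), and 52 calls were opposite (35.4 for independent lists). Neither counts against shared changes. Changes with only 1 treatment lower the correlation, and the independent lists take every probeset as equally likely to be called. The no-change medians of direction and correlation come from the simulation without a replicate term and with independent probesets. With the PACAP changes from replicates 1 and 2 and the TNF changes from replicate 3, no array in common, the covariance was 0.01972, and in the reverse arrangement 0.02266. The highest of 100 simulated data sets without effects was 0.002837 with independent probesets, but when whole arrays of residuals were drawn, which keeps probesets correlated, 5 and 7 of 100 draws reached the observed values (highest 0.0357 and 0.0464). Noise of single untreated arrays cannot produce these 2 covariances, which have no array in common, but noise common to many probesets could. If the untreated arrays were technical repeats of 1 sample, a deviation of that sample would enter both sides as well. Over all arrays, where the untreated arrays are shared, 0 of those 100 draws reached 0.0344 (highest 0.0256). These draws do not include a deviation common to all untreated arrays, and the covariances without an array in common did not decide. Whether the shared untreated arrays are the whole source, and how much of the covariance they add, therefore stays open. Handling common to both treated groups cannot be told apart from a response common to both agents for the 64 probesets higher in both, because there is no vehicle-treated group.

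Among control probesets, which the comparisons do not use, 3 differed between PACAP-treated and untreated cells (limma, adjusted p under 0.05), namely the 3' probeset of ef1a by -0.45, the 3' probeset of eIF-4E by 0.46 and the middle probeset of eIF-4E by 0.60 (log2).

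The 6 arrays of each comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05, and in each comparison 1 of the 10, the real split, gave as many calls (limma). For PACAP against untreated the real split called 3470 probesets and the highest other split 0, with up to 2678 at an unadjusted p under 0.05. For TNF against untreated the numbers were 458, 0 and 2184, and for PACAP against TNF 2179, 1 and 3683. The 3 other splits that part every same-numbered pair called 0 in each comparison, with at most 822, 1642 and 1330 probesets at an unadjusted p under 0.05. They differ from the real split in mixing the treatments on each side.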

How the results depend on the processing

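The block that parts replicates 1 and 2 from replicate 3, the averaging of replicates 1 and 2 together with the replicate block and the fit within replicates 1 and 2 were chosen after the data were seen. Of 22 other settings, 6 kept every count within 1.5 times of the reported one, and no setting called a probeset in the opposite direction. The 4 probesets with the largest rises with PACAP or TNF and the 2 with the largest falls with PACAP passed in every setting where they were tested. In what follows, counts are of higher and lower probesets. The replicate block gave 2206 higher with PACAP, 674 and 606 with TNF, 1656 and 2035 between treatments, and 189, 413 and 107 for higher in both, lower in both and opposite; it kept 3465 of the 3470 calls with PACAP, 458 of 458 with TNF and 2176 of 2179 between treatments. The block of replicates 1 and 2 against 3 gave 2430 and 3340 with PACAP, 803 and 797 with TNF (13 at least 2-fold lower), 1912 and 2294 between treatments, and 263, 556 and 129 in both. With replicates 1 and 2 averaged and the block kept, the numbers were 768 and 990, 122 and 15, 514 and 581, and 10, 6 and 12. That setting kept only 1564 of the 3470 calls with PACAP, 113 of 458 with TNF and 943 of 2179 between treatments. Within replicates 1 and 2 they were 2907 and 4001 (381 at least 2-fold lower), 1415 and 1499 (231 and 39 of at least 2-fold), 2402 and 2960, and 647, 1093 and 256. Array weights gave 2821 and 3602, 1524 and 1973 (214 and 28), 2109 and 2481, and 632, 1263 and 232. A threshold of 0.01 gave 632 and 879, 109 and 14 (77 and 4), 407 and 543, and 10, 10 and 9. Fits of 6 arrays gave 183 and 62 with TNF, and 34 and 39 in both, and kept 222 of the 458 TNF calls. Without the dimmer 50% of probesets, where fewer were tested, 84 and 4 were at least 2-fold changed with TNF. For the other changes of count the cause was not tested. Centring, repeated quantile normalization, cyclic loess, the intensity trend and the filter on the dimmest 25% moved no count by over 1.5 times.

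Leaving out 1 array gave 700 to 1729 higher and 984 to 2391 lower with PACAP, of which at least 2-fold 237 to 371 and 165 to 313. It gave 107 to 425 and 12 to 310 with TNF, of which at least 2-fold 75 to 180 and 3 to 28. The share of the 458 TNF calls kept ran from 26.2% without untreated replicate 2 to 86.9% without PACAP replicate 3. For the 3470 PACAP calls it ran from 48.5% without untreated replicate 2 to 99% without TNF replicate 3. Between treatments it gave 476 to 1267 and 630 to 1517, and for higher in both, lower in both and opposite 13 to 186, 9 to 260 and 15 to 86. A group left with 2 arrays was assumed to vary like the others. The share of rises among TNF calls ran from 43.6% with array weights to 90% without untreated replicate 2. Among PACAP calls it was 41.2% in the main fit and ran from 39.1% without PACAP replicate 3 to 49.6% with arrays centred on their medians. After that centring 1642 were higher and 1669 lower with PACAP, so the excess of falls depends on the scaling. Other background corrections and all gene list tests were not run. Signal over background could not be set per probeset, so falls of dim probesets were hard to measure.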

Other observations

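The look at control genes was chosen after the result was seen, and the test of probesets from 1 sequence cluster was set beforehand.

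Named genes could be read from 18 bovine control probesets covering 6 genes, each at its 3', middle and 5' part. eIF-4E, the cap-binding translation initiation factor, rose with PACAP at its 3' probeset by 0.46 (log2, SE 0.10), from 11.02 ± 0.17 (SD, n = 3) to 11.48 ± 0.11 (limma adjusted p = 0.0202), and at its middle probeset by 0.60 (SE 0.16), from 9.64 ± 0.27 to 10.24 ± 0.20 (limma adjusted p = 0.0373). Its 5' probeset was 0.63 higher (SE 0.22) and did not pass (limma adjusted p = 0.0997). The 3' probeset of ef1a, a translation elongation factor, fell by 0.45 on the log2 scale (SE 0.12), from 11.88 ± 0.10 to 11.43 ± 0.24 (limma adjusted p = 0.0381), while its middle and 5' probesets, at -0.44 (SE 0.26) and -0.10 (SE 0.09), did not pass. The probesets of actin, gapd, Cyph and GST did not pass with PACAP. With TNF, 0 of the 18 passed in limma, and 0 had an unadjusted p under 0.05. The 3 called control probesets kept their direction under the other scalings; centring on the medians left the ef1a 3' change at -0.40, which no longer passed (limma adjusted p = 0.0655).

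With replicates 1 and 2 averaged and the replicate block, all 3 calls were lost, at log2 changes of 0.38 for eIF-4E 3' (limma adjusted p = 0.18), 0.52 for its middle probeset (0.153) and -0.41 for ef1a 3' (0.0891). The eIF-4E 3' call was also lost without untreated replicate 1 (log2 change 0.39), untreated replicate 2 (0.42), PACAP replicate 1 (0.44) or PACAP replicate 2 (0.41), with limma adjusted p-values from 0.000851 to 0.18 over the settings. The middle eIF-4E call was lost in 9 of 22 settings, among them without untreated replicate 1 (0.50), untreated replicate 2 (0.54), PACAP replicate 2 (0.50), PACAP replicate 3 (0.60) and TNF replicate 1 or 2 (0.60). The ef1a call was lost in 11 of 22 settings, among them without untreated replicate 1 (-0.47), untreated replicate 2 (-0.48), untreated replicate 3 (-0.39), PACAP replicate 1 (-0.37), PACAP replicate 2 (-0.39) and TNF replicate 1 or 2 (-0.45).

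Probesets whose IDs share their first number were taken as designed from 1 sequence cluster; 3756 of 19291 such numbers had more than 1 probeset. Where a probeset changed at least 2-fold with PACAP, its siblings moved the same way in 92.6% of 216 pairs, against at most 60.2% in 1000 random draws matched on mean level, and 64.4% of siblings were themselves called in that direction, against at most 12.5%. With TNF, 96.3% of 82 pairs moved the same way, against at most 59.8%, and 74.4% were called, against at most 9.8%. These draws argue against chance as the source of the shared directions. Siblings of 1 transcript bear on the measurement and do not replicate the cultures.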
